A study of Homo sapiens with 6 samples.

How the data were processed

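Total RNA of 6 samples of HL60 derivatives was measured on Human Genome U133 Plus 2 arrays, which are 1-colour oligonucleotide arrays with several probe sets for many genes. The groups were 3 samples with USP2 shRNA and 3 with a negative control shRNA, taken from the sample titles. Per the labels' protocols all cells received 30 nM PMA for 1 day and 10 µg/mL LPS for 4 h, RNA was extracted with Trizol, and biotinylated cRNA was made with a 3' in vitro transcription kit. Such arrays read mainly the 3' part of a transcript, so a probe set can miss isoforms with another 3' end.

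The deposited values are intensity values on a linear scale, 1 signal per probe set and array, made with GCOS per the submitters' processing notes. The version of that software, its summary algorithm and its scaling target are not given in the sources used here. The values themselves show that every array was scaled to a mean of 500.1 after trimming 2% of probe sets at each end. Such scaling assumes that total signal is alike in all samples. Detection calls were not used here. Medians of the arrays ranged from 69.4 to 75.5. The number of arrays limits the precision.

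The table held 54675 probe sets. In the platform annotation 41091 had 1 gene symbol, 1801 had several, and 11783 had none or were controls. Of the first group, 41037 were matched by Entrez ID to current symbols, for 19775 genes. Chromosomes and gene order came from the annotation of assembly GRCh38.p14, used only for names, chromosomes and neighbours. Some list members had no probe set with 1 symbol and are not analysed here, which left 493 of 547 list memberships.

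The main setting took log2(value + 6.40), where the offset is the 10th percentile of all values, with no further normalization. Fold changes are on this scale and understate changes of dim genes. Each gene was represented by its single-symbol probe set with the highest mean over the 6 arrays, and 11777 genes with a mean above the median of all probe sets (6.06 on the log2 scale, a signal of 60.1) were tested. Where the lower group's mean log2 value lay under that level, the fold is mostly given as a bound, the brighter group's mean log2 value against the level. List genes called measured are those that passed this filter, and dimmer members on the array were left out. Of chemokines 14 of 22 on the array passed, and of interferon-stimulated genes 16 of 31. The numbers were 6 of 20 neutrophil, 5 of 15 lymphocyte and erythroid, and 7 of 14 fibroblast and epithelial markers.

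Groups were compared with limma 3.58.1 (lmFit, eBayes with trend, two-sided, adjusted by Benjamini-Hochberg over all tested genes) in R 4.3.3 with statmod 1.5.0, at an adjusted p under 0.05. Differences of USP2 probe sets and RNA quality measures were tested by exact permutation, where 3 against 3 arrays cannot go below p = 0.1. The 20 gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. They held cytokines, chemokines, NF-kB feedback and target genes, TLR4 signalling components, interferon-stimulated genes, monocyte and macrophage differentiation, promyelocyte granule genes, neutrophil markers, lymphocyte and erythroid markers, fibroblast and epithelial markers, obesity-associated macrophage genes, cell cycle, MDM2 and p53 target genes, fatty acid and cholesterol synthesis, circadian clock, deubiquitinases, proteasome subunits, unfolded protein and integrated stress response, glycolysis and hypoxia, and oxidative stress and NRF2 targets. The lists, the tests and the rule for named genes were fixed before the data were examined.

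Named genes were USP2, up to 12 genes each way with the largest log2 fold change among called genes whose arrays do not overlap, up to 4 called members of each list by smallest adjusted p, and a fixed set of inflammatory and USP2-related genes. One gene chosen by this rule is not reported here. BCL2A1, NFKB1, PPARG, LPL and CCND2 were named after their values were seen. The same holds for ITGAM, KLF4, EGR1, CD86, VDR, SPP1, CYBB and CD163, which are not part of the counts of named genes. Adjusted p-values of a named gene's further probe sets are from limma without the filter, over all single-symbol probe sets. Median changes of the 23 chromosomes with at least 100 tested genes were set against 10000 gene sets matched in 10 bins of mean expression, a test chosen after the gene results were seen.

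The procedure was tested on simulated data with 200 changed genes among 11803 tested for the comparison of USP2 shRNA with control shRNA. It recovered 44.1% of genes changed by 0.5 on the log2 scale, 72.7% of those changed by 1 and 87.9% of those changed by 2, and 9 of 145 called genes were unchanged ones. The simulated noise was independent between genes, with an SD smoothed over genes of like mean signal. Far fewer genes were changed than the 2025 called in the data, so these rates need not hold for the data. Alternatives were quantile normalization, median centring, a 4 times larger offset, a floor in place of the offset, no filter, a filter at the 75th percentile, all probe sets, the mean of a gene's probe sets, eBayes without trend, robust eBayes, array weights, the replicate number as a block, leaving out each array, a 2-fold threshold, and camera with an estimated correlation or on ranks. With all probe sets, those of 1 gene counted as separate list members in camera, which can lower a list's adjusted p. Leaving out chromosome 4 genes was added after seeing the data.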

Results

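HL60 is an established human promyelocytic leukaemia cell line that takes on macrophage-like features in the presence of phorbol 12-myristate 13-acetate (PMA), and lipopolysaccharide (LPS) is a bacterial envelope component sensed through TLR4. Derivatives of the line carried either a short hairpin RNA (shRNA) directed at USP2, a deubiquitinating enzyme, or a negative control shRNA. Both derivatives had received 30 nM PMA for 1 day and then 10 µg/mL LPS for 4 h when total RNA was taken. Gene expression was read on Human Genome U133 Plus 2 arrays, 3 for each derivative, and the comparison asked which transcripts differed when USP2 was silenced in stimulated cells. No unstimulated sample was analysed here, so every value describes cells after PMA and LPS.

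The median signal of the 6 arrays lay between 69.4 and 75.5, and the trimmed mean of every array was 500.1. The ratio of 3' to 5' GAPDH signal, a measure of RNA integrity, was 1.09 ± 0.0189 (SD, n = 3) with USP2 shRNA and 1.10 ± 0.00749 (SD, n = 3) with control shRNA (exact permutation p = 0.4, two-sided). For ACTB the ratio was 3.82 ± 0.682 and 3.90 ± 0.899 (exact permutation p = 0.9). On single arrays the ACTB ratio ran from 3.15 (control shRNA replicate 3) to 4.90 (control shRNA replicate 1), so it was well above that of GAPDH throughout. Control shRNA replicate 1 stood apart in its ribosomal RNA control probe set, with a signal of 707 against 3341 to 4054 on the other 5 arrays. Across genes, log2 values correlated at 0.979 to 0.981 within a group and at 0.966 to 0.967 between groups. The labels do not say that the 3 samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

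USP2 itself was lower in the cells carrying its shRNA. The brightest USP2 probe set read 354 ± 40.0 (SD, n = 3) with USP2 shRNA and 837 ± 120 (SD, n = 3) with control shRNA, a 2.34-fold lower signal. The log2 fold change was -1.22 (SE 0.14, adjusted p = 0.000193), and the 3 arrays of each group did not overlap (exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). The other 3 USP2 probe sets lay lower in the signal range and did not pass the test. The next brightest had a mean of 53.6 with USP2 shRNA and 146 with control shRNA (log2 fold change -1.12, exact permutation p = 0.5), the third had 29.1 and 64.1 (exact permutation p = 0.4), and the dimmest had 49.6 and 8.63 (log2 fold change 1.37, exact permutation p = 0.3).

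**Figure D1:**
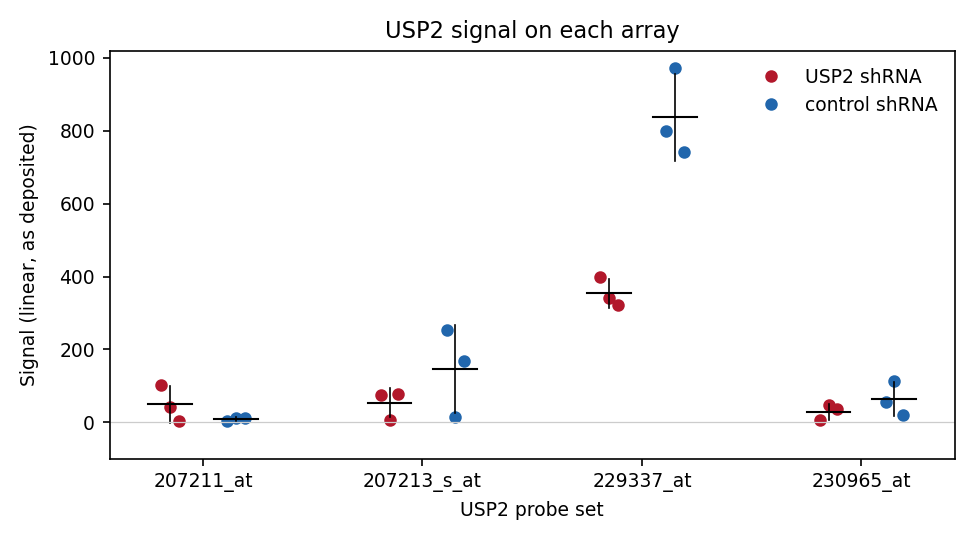
Linear signal of each USP2 probe set (vertical axis) on the 3 USP2 shRNA arrays and the 3 control shRNA arrays, with points for arrays, horizontal lines for means and vertical lines for 1 SD. Only for the brightest do the groups stand apart, with means of 354 and 837.

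USP2 shRNA went with a broad difference in expression. Of 11777 genes tested, 1047 were higher and 978 lower (adjusted p under 0.05), which is 17.2% of the genes, and 213 of the higher and 63 of the lower genes differed at least 2-fold. The arrays of the groups did not overlap for 2017 of these 2025 genes. Among all tested genes 34.2% did not overlap, where chance gives 10%. The median log2 fold change over all genes was -0.03.

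Among the genes with the largest rise, FABP4, a fatty acid-binding protein of adipocytes and macrophages, stood at 27690 ± 1371 (SD, n = 3) with USP2 shRNA against 1071 ± 47.5 (SD, n = 3), a log2 fold change of 4.68 (SE 0.06, adjusted p = 1.06e-11). A further FABP4 probe set, dim in control cells, was also higher (adjusted p = 0.000531). HMGA2, an architectural chromatin protein, and HOPX, an atypical homeodomain protein, were dim in control cells, and HMGA2 rose at least 28.8-fold and HOPX rose from 48.2 to 1524. The ubiquitin ligase genes RNF144B and HECTD2 rose at least 10.5-fold and at least 13.9-fold, and UCHL1, a deubiquitinating enzyme of neurons and many tumours, rose 9.77-fold, from 640 to 6319. The matrix metalloproteinase MMP10 rose 13.9-fold. DYNLT5 rose at least 9.86-fold, SPATS2L at least 7.49-fold, and the transcription factors HIVEP2 and TWIST1 at least 5.79-fold and at least 4.83-fold. HOPX and UCHL1 lie on chromosome 4, whose genes had a median log2 fold change of 0.29.

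The genes with the largest decrease were mostly of modest signal. CTSW, a cathepsin of cytotoxic lymphocytes, was at least 3.94-fold lower with USP2 shRNA. The natriuretic peptide gene NPPC was 5.56-fold lower, from 693 to 123, and the transcription factor gene ARNT2 was 5.55-fold lower. GDF15, a stress-induced cytokine of the TGF-beta superfamily, was 5.20-fold lower, and the lymphocyte receptor gene CD6 was 4.47-fold lower. FCGR2B, the inhibitory Fc gamma receptor, fell from 4536 ± 209 to 1376 ± 122 (SD, n = 3; log2 fold change -1.72, adjusted p = 2.64e-07), although its probes can be shared by close paralogs. SERINC5 was 3.08-fold and SH3BP5 was 3.01-fold lower, and a further SH3BP5 probe set gave a log2 fold change of -1.41. SYP fell from 246 to 67.2, and AQP2 was at least 2.56-fold lower, with a further probe set at -0.30 and not called. SCUBE1 and RAX2 passed with all 6 arrays (adjusted p = 0.0446 and 0.0402). SCUBE1 lost its call without USP2 shRNA replicate 1 or without any control array (adjusted p = 0.0859 to 0.117), and RAX2 without any array other than USP2 shRNA replicate 1 (adjusted p = 0.0623 to 0.121).

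**Figure D2:**
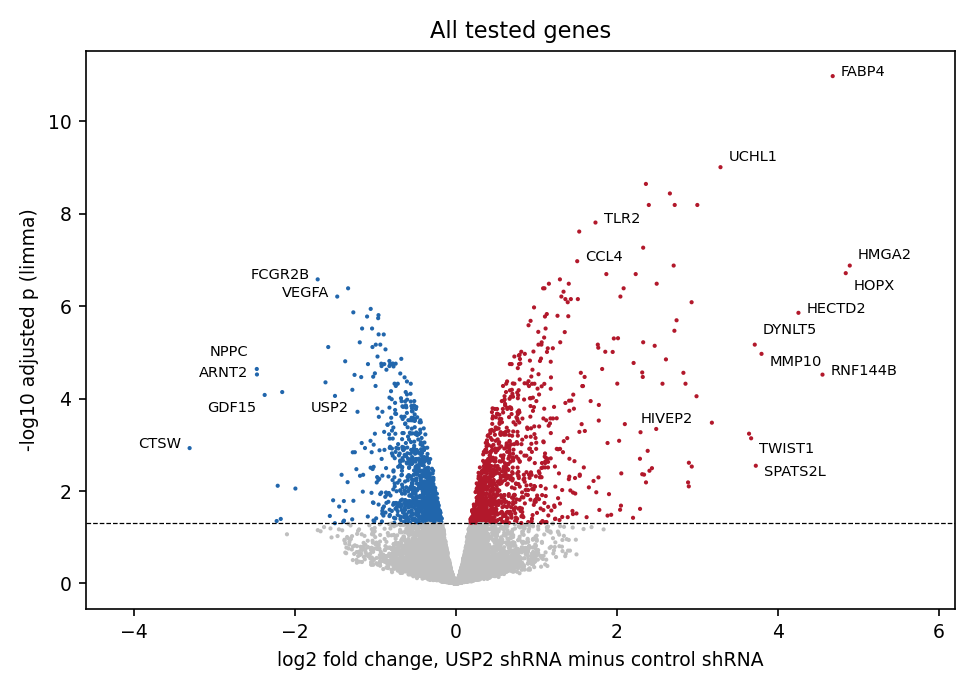
Log2 fold change, USP2 shRNA minus control shRNA (horizontal axis), against -log10 adjusted p (vertical axis) for 11777 genes, with a dashed line at an adjusted p of 0.05. Red points are the 1047 higher genes, blue points the 978 lower genes and grey points the others, and FABP4 has the smallest adjusted p, 1.06e-11.

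Genes of NF-kB feedback and NF-kB targets rose together. Of 24 measured, 17 rose, BCL2A1 fell (log2 fold change -0.29) and 6 did not pass, with 18 higher and 1 lower adjusted over the list alone. The median log2 fold change was 0.60 (camera adjusted p = 1.29e-13), and this was the 1 list that kept its call with an estimated correlation (adjusted p = 0.0196 with an estimated correlation). F3, which encodes tissue factor, rose by 1.51 on the log2 scale from 2371 to 6814, and TNFAIP6, a hyaluronan-binding protein of inflammation, rose by 1.39. The genes of the A20-binding inhibitors TNIP2 and TNIP1 rose by 1.06 and 0.73, with a further TNIP1 probe set at 0.13 and not called. PTGS2, which encodes cyclooxygenase-2, rose by 0.38 (adjusted p = 0.00226). TNIP2 and NFKB1 lie on chromosome 4, and without chromosome 4 genes the list had a median of 0.59 (camera adjusted p = 2.3e-12).

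Chemokine genes were higher as a group. Of 14 measured, 9 rose and 5 did not pass, with 10 higher adjusted over the list alone, at a median log2 fold change of 0.94 (camera adjusted p = 5.72e-10). The call was lost with adjusted p = 0.0647 with an estimated correlation. CXCL6, a neutrophil attractant, rose 5.64-fold from 253 ± 30.9 to 1449 ± 36.3 (SD, n = 3), and CXCL2 rose by 0.92 on the log2 scale. CCL4 rose 2.84-fold from 12010 to 34140, and CCL1 by 0.97. CXCL8 had a log2 fold change of 0.26 (adjusted p = 0.0656) and passed without USP2 shRNA replicate 2 (adjusted p = 0.0473). A further CXCL8 probe set, also bright, had 0.09 and was not called (adjusted p = 0.655). CCL2 had 0.13 (adjusted p = 0.33). Of the measured chemokine genes 5 lie on chromosome 4, CXCL6, CXCL2 and CXCL8 among them, and the other genes of the list had a median of 0.75 (camera adjusted p = 2.96e-05).

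Cytokine genes went both ways. Of 17 measured, 5 rose, 7 fell and 5 did not pass, with 6 higher and 8 lower adjusted over the list alone. The list was not called (camera adjusted p = 0.863, direction down), and its median of -0.07 and mean of 0.11 differed in sign. EBI3, a subunit of interleukin-27 and interleukin-35, rose 3.39-fold, IL1A rose 2.57-fold from 1316 to 3386, and TNF rose 1.64-fold (adjusted p = 0.000326). A further, dimmer IL1A probe set had a log2 fold change of -0.42 and was not called (adjusted p = 0.78). VEGFA, the angiogenic growth factor gene, fell from 2317 ± 87.4 to 829 ± 27.0 (SD, n = 3). Its other probe sets above the filter were not called, with log2 fold changes of -0.57 (adjusted p = 0.29), -0.10 (adjusted p = 0.95) and -1.17 (adjusted p = 0.396). CSF1, the macrophage colony-stimulating factor gene, fell by 0.68 on the log2 scale. IL1B had a log2 fold change of 0.10 (adjusted p = 0.361) at 64510 against 60200, and IL6 had 0.68 (adjusted p = 0.105).

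The list of TLR4 signalling components also held the other receptor genes TLR1, TLR2, TLR6 and TLR8. It had 6 higher genes among 28 measured and 22 that did not pass, with 7 higher adjusted over the list alone. The median was 0.09 (camera adjusted p = 0.0172), and the call was lost with adjusted p = 0.195 with an estimated correlation and on ranks (0.055). TLR2, the receptor for bacterial lipoproteins, rose 3.33-fold from 6263 ± 211 to 20850 ± 829 (SD, n = 3), and its partner gene TLR1 rose by 0.59 on the log2 scale. The kinase gene IRAK2 rose by 0.73 and the adaptor gene TAB2 by 0.43. The LPS co-receptor gene CD14 rose at least 1.82-fold (adjusted p = 0.027), and this call was lost without any array other than control shRNA replicate 1 (adjusted p = 0.0579 to 0.113). TLR4 had 0.26 (adjusted p = 0.13). TLR2 and TLR1 lie on chromosome 4, and without the genes of that chromosome the list was not called (camera adjusted p = 0.122).

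Interferon-stimulated genes were not called as a list (16 measured, median 0.17, camera adjusted p = 0.0699), and passed without USP2 shRNA replicate 2 (adjusted p = 0.035), without chromosome 4 genes (0.0494), with no filter (0.035), with all probe sets (0.0155) and without the variance trend (0.0442). In this list 16 of 31 genes on the array passed the filter. Of these, 3 rose and 13 did not pass the test, with 4 higher adjusted over the list alone. IFI44 rose at least 2.50-fold. IFIT3 rose by 0.63 on the log2 scale, with a further probe set at -0.07 and not called, and GBP2 rose by 0.69. Without 1 array the calls of IFIT3 (without any array other than control shRNA replicate 1) and GBP2 (without USP2 shRNA replicate 1 or 2 or control shRNA replicate 2) were lost, at adjusted p = 0.0533 to 0.0929 and 0.0869 to 0.144.

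Macrophage genes associated with obesity had 6 higher, 4 lower and 8 genes that did not pass among 18 measured, with 7 higher and 4 lower adjusted over the list alone. Published work on USP2 in macrophages, which may rest on these samples, was known when FABP4 was put on this list, so the list is not independent evidence of its direction. The median was 0.24 (camera adjusted p = 0.00919), and the call was lost with adjusted p = 0.15 with an estimated correlation, with a filter at the 75th percentile (0.104) and on ranks (0.0667). Beside FABP4, the protease inhibitor gene SERPINE2 rose 6.69-fold, from 109 to 761, and NAMPT, which encodes an enzyme of NAD synthesis, rose by 0.81 on the log2 scale. CD36, a scavenger receptor for oxidised lipoproteins, fell by 0.56. PPARG, the nuclear receptor gene, had a log2 fold change of -0.52 and LPL, the lipoprotein lipase gene, had -0.32, and both calls passed.

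Cell cycle genes were higher with USP2 shRNA. Of 35 measured, 17 rose, CCND2 fell (log2 fold change -0.98) and 17 did not pass, with 20 higher and 2 lower adjusted over the list alone. The median was 0.50 (camera adjusted p = 4.72e-09), and the call was lost with adjusted p = 0.0647 with an estimated correlation. CDK1, the mitotic kinase gene, rose from 1483 ± 263 to 3330 ± 168 (SD, n = 3). UBE2C, which encodes a ubiquitin-conjugating enzyme of mitosis, rose by 0.88 on the log2 scale, TOP2A by 0.93 and the thymidylate synthase gene TYMS by 0.78. CCND1 had -0.10 (adjusted p = 0.557).

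Genes of MDM2 and the p53 pathway were not called as a list (19 measured, 3 higher and 1 lower, the same numbers adjusted over the list alone; camera adjusted p = 0.855). The test pointed up while the median was -0.04 and the mean -0.01. GADD45A rose by 0.64 and TIGAR fell by 0.31 on the log2 scale, and MDM2, a USP2 substrate in the literature, had 0.06 (adjusted p = 0.789). TNFRSF10B and CCNG1, at 0.20 and 0.22, lost their calls without any 1 of the 6 arrays (adjusted p = 0.072 to 0.123 and 0.0696 to 0.131).

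Genes of glycolysis and the hypoxia response were lower as a list. Of 26 measured, 7 fell, 3 rose and 16 did not pass, with 9 lower and 3 higher adjusted over the list alone. The median was -0.15 (camera adjusted p = 0.026), and the call was lost with adjusted p = 0.174 with an estimated correlation, without USP2 shRNA replicate 2 (adjusted p = 0.0504) and without control shRNA replicate 3 (adjusted p = 0.0564). It was also lost with a filter at the 75th percentile (adjusted p = 0.0768), with the mean of a gene's probe sets (0.156), without the variance trend (0.055) and on ranks (0.055). HK2, which encodes hexokinase 2, fell from 6752 ± 1061 to 2803 ± 332 (SD, n = 3), with its other probe sets at -0.93 and -0.92 and not called, PFKFB4 fell by 0.89 on the log2 scale, and BNIP3L rose by 0.47.

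Oxidative stress genes and NRF2 targets had 8 higher genes, 1 lower gene and 14 that did not pass among 23 measured, with the same 8 and 1 adjusted over the list alone. The median was 0.12 (camera adjusted p = 0.00643), and the call was lost with adjusted p = 0.195 with an estimated correlation. NQO1 rose by 0.45, GCLM by 0.41 and TXNRD1 by 0.35 on the log2 scale, with a further GCLM probe set at 0.09 and not called. The lower gene was HMOX1, which encodes haem oxygenase 1, and fell from 2792 ± 417 to 991 ± 237 (SD, n = 3). Genes of the unfolded protein and integrated stress response were not called as a list (24 measured, 3 higher and 8 lower, and 3 higher and 9 lower adjusted over the list alone; median -0.12, camera adjusted p = 0.201), and passed as lower with all probe sets (adjusted p = 0.0155). DDIT4 rose 2.66-fold and ATF3 by 0.28 on the log2 scale, while XBP1 and TRIB3 fell by 0.40 and 0.47.

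Markers of myeloid differentiation moved in both directions. In the monocyte and macrophage list 5 of 29 measured genes rose, 8 fell and 16 did not pass, with 6 higher and 11 lower adjusted over the list alone (median -0.09, camera adjusted p = 0.0982). This list passed as lower without control shRNA replicate 1 (adjusted p = 0.0478), with a filter at the 75th percentile (adjusted p = 0.0458) and with all probe sets (adjusted p = 0.0155). Besides FCGR2B and CD36, which fell, TFEC rose by 1.04 and MSR1 by 0.45 on the log2 scale. Further MSR1 probe sets above the filter had -0.43, -0.06 and 0.23 and were not called. The other lower genes were ITGAM, KLF4, EGR1, CD86, VDR and SPP1, and the other higher genes were CYBB, CD163 and CD14. In the promyelocyte granule list 4 of 14 genes rose and 2 fell, with 5 higher and 2 lower adjusted over the list alone (median 0.21, camera adjusted p = 0.144), and this list passed as higher with all probe sets (adjusted p = 0.0155). RNASE2, which encodes an eosinophil granule ribonuclease, rose 2.70-fold, the transcription factor gene MYB rose by 0.82 and MS4A3 by 0.66 (a further MS4A3 probe set had 0.39 and was not called), and CST7 fell by 0.75. Neutrophil markers had 1 higher gene among 6, and 1 adjusted over the list alone (median 0.34, camera adjusted p = 0.431). That gene, S100A8, lost its call without USP2 shRNA replicate 1 or 2 or control shRNA replicate 1 or 3 (adjusted p = 0.0933 to 0.162). Lymphocyte and erythroid markers (5 measured, median 0.12, camera adjusted p = 0.803) and fibroblast and epithelial markers (7 measured, camera adjusted p = 0.855) had 0 genes called by limma, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05. For the latter list the median was 0.05 while the mean was -0.02 and the test pointed down.

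Deubiquitinase genes other than USP2 were not called as a list. Of 41 measured, 9 rose, 4 fell and 28 did not pass, with 10 higher and 5 lower adjusted over the list alone (median 0.04, camera adjusted p = 0.0982), and the list passed as higher with no filter (adjusted p = 0.0433). UCHL1 rose most, CYLD rose by 0.59 and TNFAIP3 by 0.36 on the log2 scale, and UCHL3, on chromosome 13, fell by 0.36. Further CYLD probe sets above the filter had 0.47, 0.44, 0.60 and -0.34. They were not called in the limma fit without the filter (adjusted p = 0.0569 to 0.786). Proteasome subunit genes had 2 higher and 1 lower among 31, and 1 and 1 adjusted over the list alone (camera adjusted p = 0.736). PSMD4 rose by 0.31. PSMD1 and PSMD11, at -0.30 and 0.31, lost their calls without 1 array in 2 and 5 of the 6 cases (adjusted p = 0.0717 to 0.0892 and 0.0648 to 0.119).

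Fatty acid and cholesterol synthesis genes had 3 higher and 2 lower among 16, the same numbers adjusted over the list alone (camera adjusted p = 0.633). SCD, the stearoyl-CoA desaturase gene, fell by 0.88 on the log2 scale, with a further probe set at -0.20 and not called (adjusted p = 0.71), and SC5D fell by 0.54, while INSIG1 rose by 0.67 and ACSL1, on chromosome 4, by 0.76. FASN had -0.08 (adjusted p = 0.88). Circadian clock genes had 2 higher and 2 lower among 12, and 3 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.834, direction down, with a median of -0.16 and a mean of 0.12). BMAL1, the core activator of the clock, rose at least 3.89-fold. The smaller changes of BMAL2, CRY1 and TEF lost their calls without 1 array in 5, 5 and 4 of the 6 cases (adjusted p = 0.0806 to 0.13, 0.0703 to 0.135 and 0.0826 to 0.163).

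**Figure D3:**
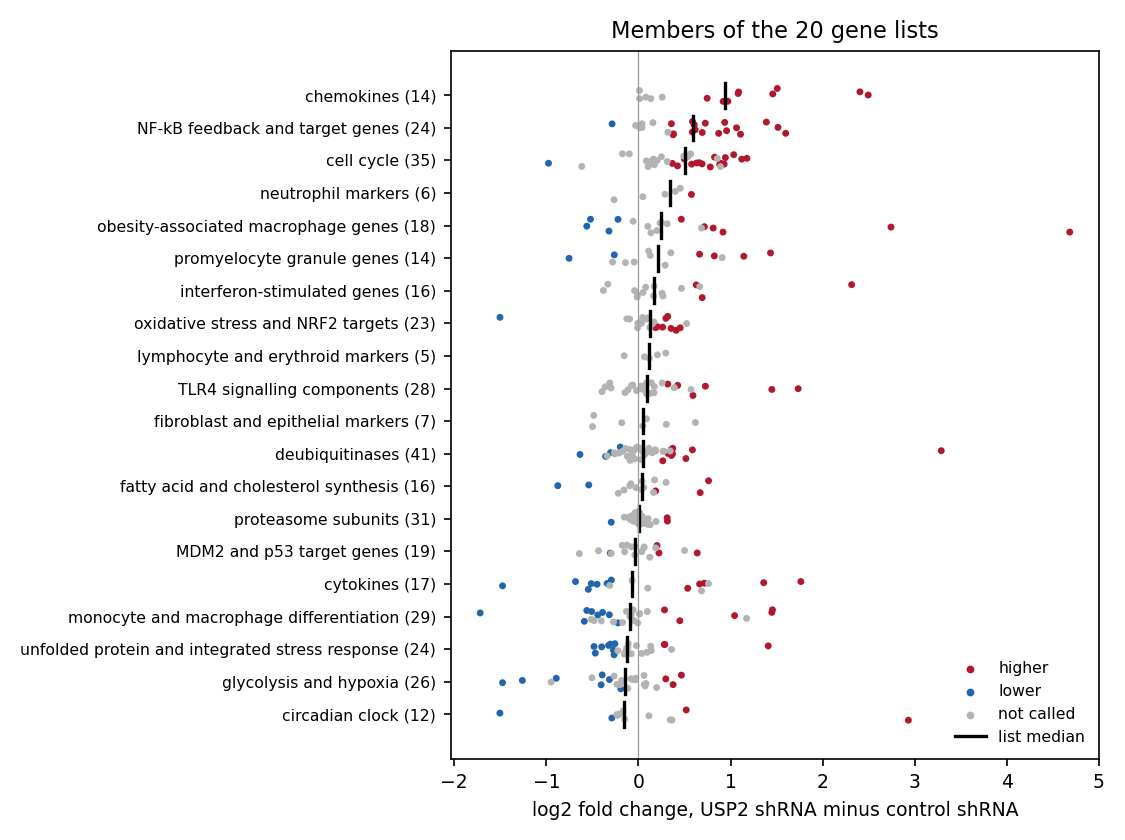
Log2 fold change, USP2 shRNA minus control shRNA (horizontal axis), of each measured member of the 20 gene lists (number of genes in brackets), with red points for higher, blue for lower and grey for other genes and black bars for list medians. Chemokines lie highest with a median of 0.94, followed by NF-kB genes at 0.60 and cell cycle genes at 0.50.

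Expression also differed by chromosome. The 418 tested genes of chromosome 4 had a median log2 fold change of 0.29, 79.4% of them were above 0, and 147 were higher and 8 lower. None of 10000 gene sets matched on mean expression reached that median (permutation p = 1e-04, the smallest these draws can give). Over 23 chromosomes the adjusted permutation p was 0.000575. The draws permuted genes and not arrays, so the chromosome p-values treat genes as independent and do not measure the spread between arrays. An exact permutation of the 6 arrays cannot go below p = 0.1. Relative to the mean of the 6 arrays, chromosome 4 genes lay at 0.14 to 0.17 on every USP2 shRNA array and at -0.16 to -0.13 on every control shRNA array. Genes of chromosome 18 (median -0.19) and chromosome 13 (median -0.14) were lower, both with adjusted p = 0.000575. Chromosomes 16 and 19 were lower by less (median -0.09, adjusted p = 0.000575, and -0.07, adjusted p = 0.00138). For both, control shRNA replicate 1, the array with the low ribosomal RNA control signal, lay farthest out, at 0.108 and 0.112. Control shRNA replicates 2 and 3 lay at 0.0546 and 0.0294 on chromosome 16, and at 0.053 and -0.000323 on chromosome 19. The USP2 shRNA arrays lay at -0.0458 to -0.00986 on chromosome 19. Without chromosome 4 genes, 887 genes were higher and 952 lower, and 7 lists were called, an alternative chosen after seeing the data.

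**Figure D4:**
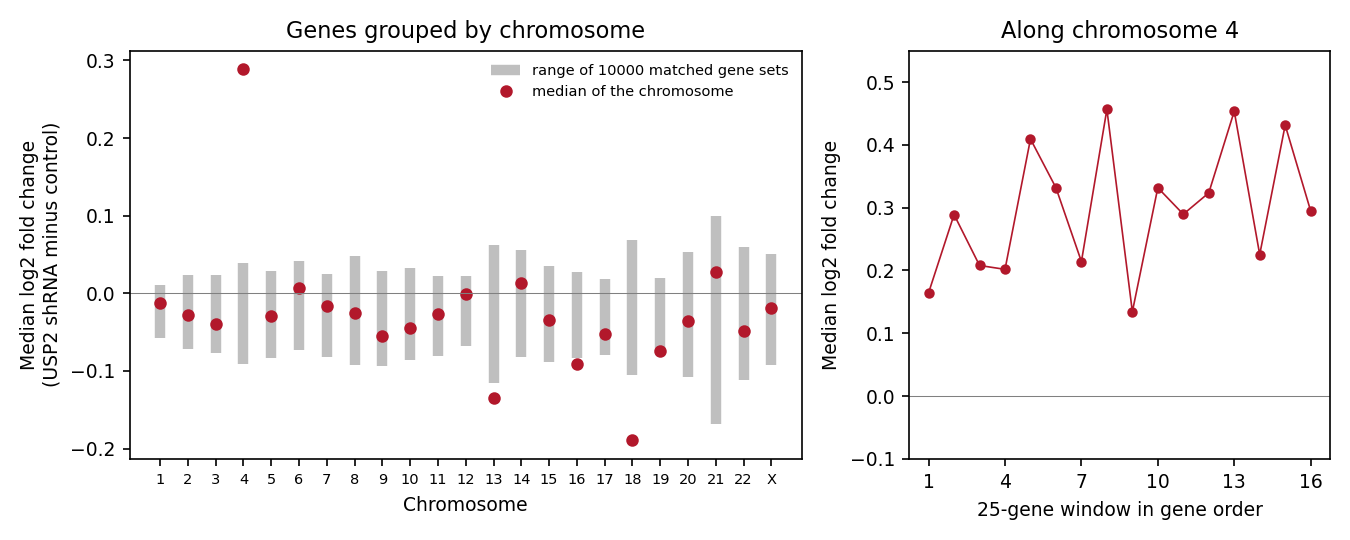
Left, median log2 fold change (USP2 shRNA minus control shRNA) of the tested genes of each chromosome as red points, with grey bars for the range over 10000 expression-matched gene sets. Right, medians of consecutive 25-gene windows along chromosome 4, which all lie above 0, from 0.13 to 0.46.

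The counts of changed genes depended on the variance model and on how probe sets were combined. Without the trend in the variance model 641 genes were higher and 494 lower, with the mean of a gene's probe sets 546 and 490, and without USP2 shRNA replicate 1 the lower genes numbered 612.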

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

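The test of probe sets outside the gene comparison was chosen after the gene results were seen. Probe sets with no gene symbol or with several, 13522 without controls, took no part in the comparison of genes, and 5317 of them passed the same filter. Among these, 100 were higher with USP2 shRNA and 78 lower (limma, adjusted p under 0.05), which is a signal in data outside the comparison of genes. Of the higher ones, 1 went from a signal of 17.4 to 289 and another from 21.5 to 248, and their control means lie under the filter level of 60.1, so the size of these changes is not given. Of the lower ones, 1 went from 328 to 143. Their genes are not named here.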

How the results depend on the processing

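The 1047 higher and 978 lower genes stayed within 1.5 times of those numbers under quantile normalization (1080 and 1014), median centring, both other offsets, other filters, all probe sets, robust eBayes and array weights. They fell to 546 and 490 with the mean of a gene's probe sets, where fewer genes (10404) were tested, to 641 and 494 without the variance trend, and to 213 and 63 with a 2-fold threshold. Leaving out each array in turn gave 736 to 998 higher and 612 to 823 lower genes, the lowest number without USP2 shRNA replicate 1, with fewer samples. Among genes called in both, 1 had the opposite direction with all probe sets and 0 under the other settings. USP2 kept its direction, but its next brightest probe set gave -1.12 (adjusted p = 0.53) and the mean of its probe sets -0.49 (adjusted p = 0.365), where dim probe sets enter the mean. The 7 called lists became 11 with all probe sets, 1 with an estimated correlation and 4 on ranks. With all probe sets, those of 1 gene counted as separate list members at the preset correlation, so the further calls are not independent support. The estimated correlations of obesity-associated genes (-0.00249) and glycolysis (-0.0167) lay under the preset 0.01. A higher correlation therefore cannot account for the calls these lists lost with it. Those of chemokines (0.0645), TLR4 signalling (0.0423), cell cycle (0.0402) and oxidative stress genes (0.0465) lay above the preset. Beyond that, the cause of the other changes was not tested. The lists lost on ranks were TLR4 signalling (adjusted p = 0.055), obesity-associated genes (0.0667) and glycolysis (0.055).

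With all probe sets the direction reversed, with no call, for IL1A (-0.42), IFIT3 (-0.0724), CD36 (0.0519), MSR1 (-0.43 and -0.0558), TNFRSF10B (-0.10), CYLD (-0.34) and TRIB3 (0.17), and with the mean of probe sets for TAB2 (-0.15); the cause was not tested. Of the named genes 13 lost their call without at least 1 array, 16 without the variance trend, 11 with no filter, 23 with the mean of probe sets, 5 with median centring, 3 with array weights, 2 with robust eBayes and 2 with a floor in place of the offset, and with all probe sets 25 of their probe set values kept the direction but not the call. CXCL8 passed under quantile normalization, median centring and array weights, but its further probe set was not called in the fit without the filter (0.09, adjusted p = 0.655).

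Deviations of same-numbered arrays correlated at 0.027, 0.025 and 0.0072 across genes. Arrays with different numbers were not compared, so this cannot exclude that same-numbered samples were handled together. With the replicate number as a block 951 genes were higher and 889 lower, USP2 stood at -1.22, 7 lists were called and 5 named genes lost their call. Values under a signal of 60.1 limit what can be said of dim genes.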

Other observations

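The genes in this paragraph were chosen after their values were seen. PPBP, the platelet basic protein gene, rose from 316.5 ± 12.2 to 2576 ± 58.1 (SD, n = 3; adjusted p = 6.48e-09), KITLG, the stem cell factor gene, rose from 111 to 758, and PDGFC, a platelet-derived growth factor gene, rose 5.02-fold. PPBP and PDGFC lie on chromosome 4. The matrix metalloproteinase gene MMP7 rose 5.14-fold to a signal of 15330, and KYNU, which encodes kynureninase of tryptophan breakdown, rose 5.27-fold. The complement receptor gene C3AR1 rose 2.03-fold. SOAT1, which encodes an enzyme of cholesterol esterification, fell from 2958 ± 161 to 1217 ± 44.3 (SD, n = 3; adjusted p = 1.36e-06), and NPC1, which encodes a lysosomal cholesterol transporter, fell from 5409 to 2591. NPC1 lies on chromosome 18.

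The grouping by chromosome, the test of windows, the test of a chromosome copy difference, the test of differentiation and the lists without chromosome 4 genes were chosen after results were seen. Chromosome 4 genes were higher as a whole. Against a bias with expression level, no matched gene set reached their median (permutation p = 1e-04 over genes, not arrays, the smallest possible). Against a few co-regulated clusters, 100% of the 16 windows of 25 genes lay above 0, where 37.5% did on other chromosomes. Against 1 deviating array, the lowest median without an array was 0.2778. A candidate explanation is that the USP2 shRNA line carried more copies of chromosome 4 than the control line, since the brighter and the dimmer genes shifted alike (0.26 and 0.3159, with matched sets reaching at most 0.09), and all 9 windows of chromosome 13 and all 6 of chromosome 18 lay below 0. DNA was not measured here, and an effect of USP2 silencing on these genes stays open and untested.

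NF-kB genes and chemokines were higher, the latter not called with an estimated correlation (adjusted p = 0.0647, and 0.0196 for NF-kB genes). Against the shift of their own chromosome 4 members as the whole cause, their medians without chromosome 4 genes were 0.5856 and 0.7456, above the shift of 0.29. Leaving out these members cannot show whether higher chromosome 4 genes, TLR2 and NFKB1 among them, acted on genes of other chromosomes. That was not tested. Less complete PMA differentiation of the USP2 shRNA line stays open. Cell cycle genes were not part of the test of differentiation. They were higher as a list (camera adjusted p = 4.72e-09, and 0.0647 with an estimated correlation). The monocyte and macrophage list (camera adjusted p = 0.09822, lower) and the promyelocyte list (camera adjusted p = 0.144, higher) missed the threshold, and genes went both ways in each. Both lists passed with all probe sets (0.0155 each), where probe sets of 1 gene counted as separate members. An effect of USP2 silencing itself may account for the difference, and with 1 line per shRNA it cannot be told apart from differences in differentiation between the lines. An off-target effect of the single USP2 hairpin was not tested and stays open for every difference reported here.

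Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many called genes as the real one, which was the real one itself, with 2025 genes, and the highest other had 0 (limma; 228 to 385 genes at an unadjusted p under 0.05 in the other splits and 3470 in the real one). A design of 10 splits is too small for a share under 0.05. Every other split also mixes both shRNA groups on each side, so the real difference widens its spread and few calls could arise there.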
